A study of Oryctolagus cuniculus with 27 samples.

How the data were processed

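Bulk RNA sequencing of 27 libraries from male New Zealand rabbits was used: 16 of aortic valve cusps, 5 of ascending aorta and 6 of left ventricular myocardium. The animals ate either normal chow or a diet with 1% cholesterol and 3500 IU of ergocalciferol (vitamin D2). The values were expected counts, that is reads assigned to each gene by RSEM, deposited by the authors in 4 tables, 1 per tissue and a second valve table from which genes named as myocardial had been taken out. Per the submitters' processing notes the tools were FastQC 0.11.9, Trim Galore 0.6.6, STAR 2.7.8a, RSEM 1.3.3 and edgeR 3.42.4. The genome build, the annotation and whether reads were counted by strand are not given in the sources used here, so antisense reads cannot be ruled out at any gene and no coordinates are given. Of the valve values, 10.1% were not whole numbers, and all values were rounded to whole counts before fitting. Genes are named by the symbols in the tables. Totals ran from 8.458 to 19.999 M counts per valve library, 11.510 to 16.107 M per aorta library and 13.954 to 17.322 M per myocardium library. Levels of single genes are given as CPM, counts scaled to the library total. Counts are reads, not molecules, since the sources name no molecular identifiers.

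The groups followed the labels: valve control (n = 4), valve after 2, 4 and 7 weeks of diet (n = 4 each), aorta control (n = 3) and diet (n = 2), and myocardium control (n = 3) and diet (n = 3). The design text says that control valves from 2 and 4 weeks were pooled, while the titles of the 4 control libraries name 7 weeks for 3 of them and 2 weeks for 1, so the age of the controls is uncertain. The labels give no duration for aorta and myocardium. By the animal numbers in the library names, all 3 diet myocardium libraries come from 7-week valve animals and 2 control myocardium libraries from control valve animals. Of the 2 diet aortas, 1 comes from a 2-week valve animal and 1 from an animal without a valve library, whose duration is not given. The fits did not model this sharing, except in an alternative with the animal as a block. The library names carry sequencing numbers: 1 to 4 for the 7-week group, 27 to 30 for the 2-week group, 31 to 34 for the controls, 36 to 38 for 4-week replicates 2 to 4 and 21 for 4-week replicate 1. The 7-week numbers lie farthest from the others. Whether they had a run of their own is not given, and if they did, run and group cannot be separated.

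Each comparison used edgeR 4.0.16 in R 4.3.3: filterByExpr by group with a minimum count of 10 and a minimum total of 15, TMM scaling, a quasi-likelihood fit and its F test, two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The 16 valve libraries shared 1 fit on the table without myocardial genes, in which 31000 of 31346 genes are listed. Differences of the diet effect between tissues were tested as such, in joint fits of valve with myocardium and of valve with aorta. For the aorta the mean of the 3 valve durations was taken. All fold changes are log2, diet minus control or later minus earlier, with the standard error (SE) of the fit; averages of CPM carry the standard deviation (SD).

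The gene lists were fixed before the data were examined: cholesterol biosynthesis, LXR targets and cholesterol efflux, macrophage, lipid-laden macrophage, T and B lymphocyte, neutrophil, leukocyte adhesion and cytokines, interferon response, osteogenic and chondrogenic, mineralisation inhibitors, vitamin D response, extracellular matrix proteins, matrix proteases and inhibitors, TGF-beta response, smooth muscle and myofibroblast, cell cycle, unfolded protein and integrated stress response, NRF2 oxidative stress response, oxidative phosphorylation, fatty acid oxidation, hypoxia and glycolysis, lysosome, complement, NOTCH and WNT signalling, endothelial, valve interstitial and fibroblast, cardiomyocyte, adipocyte, erythroid, Schwann cell and neural, melanocyte, mesothelial and epithelial, and immediate early genes. Members were matched by the symbols in the tables. Of 795 entries 100 were absent by symbol, and 39 of these appear under a LOC number that the RefSeq gene table pairs with the symbol, among them 14 of oxidative phosphorylation and C1QA and C1QB of macrophages. A list needed at least 3 tested members. Each was tested against all other genes with camera (limma 3.58.1) at a preset correlation of 0.01, adjusted over the lists of a comparison, then with the correlation estimated from the data. The lists were also tested with fry, which asks a different question, whether a list changed at all. Members past the threshold are counted over all genes tested and also adjusted over the list alone. Some genes are in more than 1 list.

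The genes named were also chosen by a rule fixed before the data were examined, among genes with a symbol. Part 1 took the 6 higher and 6 lower genes with the largest changes among those past the threshold, with a mean of at least 5 CPM and groups that did not overlap. Part 2 took the 4 smallest p in each direction not already taken. Part 3 took up to 4 members, by p, of each list that passed camera or had at least 3 members past the threshold. Part 4 named 17 genes whatever their result, of which CYP24A1, the vitamin D 24-hydroxylase, appears in the tables as LOC100347441 and was too low to be tested. Some genes that these rules chose are not reported here. Comparisons between durations and between tissues used parts 1 and 3.

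Similarity of the diet effect between weeks was the Pearson correlation and covariance of log2 fold changes across genes, which are not independent replicates, beside 20 simulated sets in which unchanged groups were compared with the same controls. The procedure was tested on simulated counts in which 100 genes changed 2-fold and 100 changed 4-fold. At 4-fold, edgeR recovered 75% at 2 weeks, 77% at 4 weeks, 78% at 7 weeks, 78% between 2 and 4 weeks, 80% between 4 and 7 weeks, 79% in the aorta, 67% in the myocardium, 58% for the difference of valve and myocardium and 45% for that of valve and aorta. At 2-fold the shares were, in the same order, 35%, 22%, 32%, 31%, 47%, 13%, 5%, 7% and 12%.

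The alternatives fixed before the data were examined were DESeq2 1.42.0, RLE size factors, no low-count filter, a mean of at least 1 CPM, the replicate number as a block, the valve table before the removal of myocardial genes, cardiomyocyte and adipocyte scores as covariates, fits with only the groups compared, other definitions of presence, control libraries split between the comparisons, and each library left out in turn. A score was the mean log2 of CPM plus 1 over the genes of its list. Covariates for erythroid and atrial genes (MYL4, MYL7 and NPPA), a fit without the 2 libraries with the most MYH6, a fit without the 7-week group, the share of RN18S in the counts as a covariate, the animal as a block in the valve and myocardium libraries of 5 animals and the same libraries without it, lists with members also matched by gene number and presence as kept by filterByExpr were added after seeing the data. No column of the tables was left out.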

Results

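RNA was sequenced from aortic cusps, ascending aorta and left ventricular myocardium of rabbits on chow or the diet, a model of early valve calcification. Each valve group (control and 2, 4 and 7 weeks of diet) had 4 libraries, aorta 3 control and 2 diet, myocardium 3 of each.

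Heart muscle transcripts were present in every valve library, in amounts that varied within and between groups. Genes of the cardiomyocyte list, such as myosins, troponins and titin, took 2.51% ± 1.46 (SD, n = 4) of the counts in control valves, 0.410% ± 0.254 at 2 weeks, 1.74% ± 1.46 at 4 weeks and 3.04% ± 1.81 at 7 weeks. The means were 0.139% and 0.204% in control and diet aortas, and 10.6% and 11.0% in control and diet myocardium. The authors took 346 genes, 1.104% of 31346, out of the valve table as myocardial, and 0 of the 24 cardiomyocyte genes listed in the tables were among them. The design text gives 2.22%. Of the 346 genes, 296 had a higher mean in myocardium than in valve, and SELE, an endothelial adhesion molecule, THRSP, an adipocyte gene, and HEMGN, an erythroid gene, were the members of the gene lists among them. Genes kept by filterByExpr in valve and myocardium but not in aorta numbered 685, or 2.19%, a definition tried after seeing the data, and 303 of the 346 were among these.

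**Figure D1:**
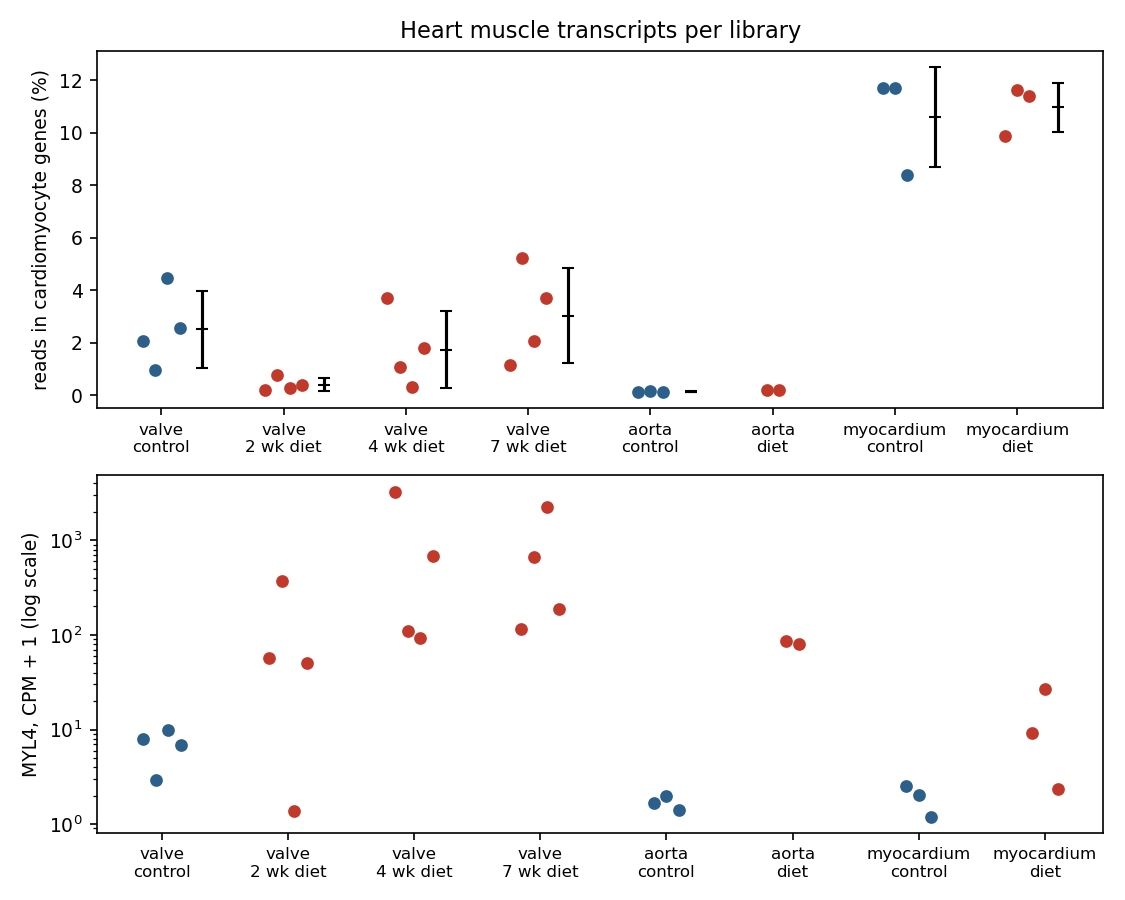
Share of counts in cardiomyocyte genes (top, percent) and CPM plus 1 of MYL4, the atrial myosin light chain (bottom, log scale), for each library by group; blue points are controls and red points diet, and in the top panel the bar is the mean with SD for groups of at least 3 libraries. The share in control valves averaged 2.51% and that in the 2-week valves 0.410%.

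After 2 weeks of diet the valves (n = 4 against 4 controls) had 4 genes past the threshold. ATP10A, a phospholipid flippase, rose 2.64-fold (1.40 ± 0.20 on the log2 scale, here and below ± SE), C1QTNF7, a secreted C1q-related protein, rose 2.54-fold (1.34 ± 0.19), and PKD1, polycystin-1, rose 1.90-fold (0.92 ± 0.15). In each, all 4 diet libraries lay above all 4 controls. LOC100344175, named after its value was seen because the count is small, fell by 1.66 ± 0.22. Adjusted p was 0.0194 to 0.0491 over the 4 genes. ATP10A and PKD1 no longer passed without 2-week replicate 1 or 3 or control replicate 1, 3 or 4, PKD1 also without 2-week replicate 4, and C1QTNF7 without 2-week replicate 3 or control replicate 3 or 4.

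Genes of the TGF-beta response stood higher as a set at 2 weeks, in cusps with less heart muscle. Diet and tissue mix are not separated. All 20 tested had positive fold changes (median 0.65). Over all genes 0 passed, and 15 adjusted over the list alone. ID1, a BMP target, stood at 1.305 ± 0.28 and BAMBI, a decoy receptor for TGF-beta, at 1.27 ± 0.29. The camera adjusted p was 1.99e-14, and adjusted p = 0.0397 with an estimated correlation. Extracellular matrix proteins had a median of 0.52, with 0 of 43 past the threshold over all genes and 15 higher adjusted over the list alone (adjusted p = 1.29e-09 by camera, adjusted p = 0.336 with an estimated correlation). Among them were the elastic fibre genes ELN (1.87 ± 0.39) and FBLN5 (0.96 ± 0.23) and the crosslinking enzyme LOX (1.5 ± 0.34). Immediate early genes, which respond within minutes to stimulation or to handling of tissue, had a median of 0.88, with 0 of 21 past the threshold over all genes and 9 adjusted over the list alone (adjusted p = 9.13e-08, adjusted p = 0.230 with an estimated correlation). FOS stood at 3.88 ± 0.79 and EGR1 at 2.13 ± 0.49. Without 2-week replicate 3, highest for FOS, they stood at 2.50 ± 0.57 and 1.11 ± 0.28. Mineralisation inhibitors had a median of 0.59, with 0 of 15 past the threshold and 2 adjusted over the list alone, including TNFRSF11B, the osteoprotegerin gene (1.03 ± 0.28). For that list camera gave adjusted p = 0.00110, and adjusted p = 0.230 with an estimated correlation.

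Mitochondrial genes stood lower as sets at 2 weeks, together with heart muscle genes. Of 38 oxidative phosphorylation genes, 0 passed over all genes and 36 were lower adjusted over the list alone, with a median of -1.24. NDUFA5, of respiratory complex I, stood at -1.37 ± 0.30 and ATP5F1C, of the ATP synthase, at -1.45 ± 0.34. Of 24 fatty acid oxidation genes, 0 passed over all genes and 13 were lower adjusted over the list alone, with a median of -0.84 and HADHB at -1.69 ± 0.39. In the same libraries cardiomyocyte genes had a median of -2.64, with 0 of 24 past the threshold over all genes and 2 higher and 18 lower adjusted over the list alone. CKMT2, a muscle creatine kinase, stood at -3.82 ± 0.88 and MYBPC3 at -3.25 ± 0.75. Atrial MYL4 was at 49.6 to 364 CPM except in replicate 3 (controls at most 8.88). The camera adjusted p was 1.23e-27, 1.12e-08 and 4.12e-14 for the 3 lists; in that order it was adjusted p = 0.302, 0.336 and 0.314 with an estimated correlation. Camera also ranked higher the smooth muscle and myofibroblast (median 0.57), cell cycle (0.18), unfolded protein (0.21) and lysosome (0.18) lists. It ranked lower the endothelial (-0.33, with a mean of 0.01 of the other sign), erythroid (-0.81) and Schwann cell (-0.50) lists. For these 7, adjusted p = 0.554 to 0.869 with an estimated correlation. Macrophage genes had a median of -0.09, with 0 of 16 past the threshold on either count.

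Values at 2 weeks of the genes named whatever their result were -0.06 ± 0.42 for the cholesterol exporter ABCA1, 1.31 ± 0.39 for SPP1, osteopontin, -0.08 ± 0.38 for CD68 and 0.29 ± 0.33 for VCAM1. They were -0.80 ± 0.42 for RUNX2, the osteoblast transcription factor, 0.05 ± 0.38 for the alkaline phosphatase ALPL, 0.05 ± 0.28 for BMP2, 0.45 ± 0.40 for SOX9 and 0.59 ± 0.30 for the calcification inhibitor MGP. The remaining values were 0.80 ± 0.31 for ACTA2, 0.86 ± 0.36 for COL1A1, -1.54 ± 1.07 for MMP9, 1.47 ± 0.81 for IL1B and -3.86 ± 0.90 for MYH7; 0 of these 14 passed by edgeR. CYP24A1, listed under LOC100347441, had at most 14 counts in any library and was too low to be tested in any tissue. The test called 4 of 15627 genes (2495 at an unadjusted p under 0.05) and DESeq2 called 911. Without 2-week replicates 1, 2 and 3 the count was 1, 71 and 0, and without control replicates 1 to 4 it was 2, 437, 1 and 0, with 1918 and 1937 genes at an unadjusted p under 0.05 in the fits that called 0. With the cardiomyocyte score as a covariate 0 genes passed (860 at an unadjusted p under 0.05), and 397 passed in a fit of the 8 libraries alone. With the share of RN18S as a covariate, chosen after seeing the data, 539 passed.

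**Figure D2:**
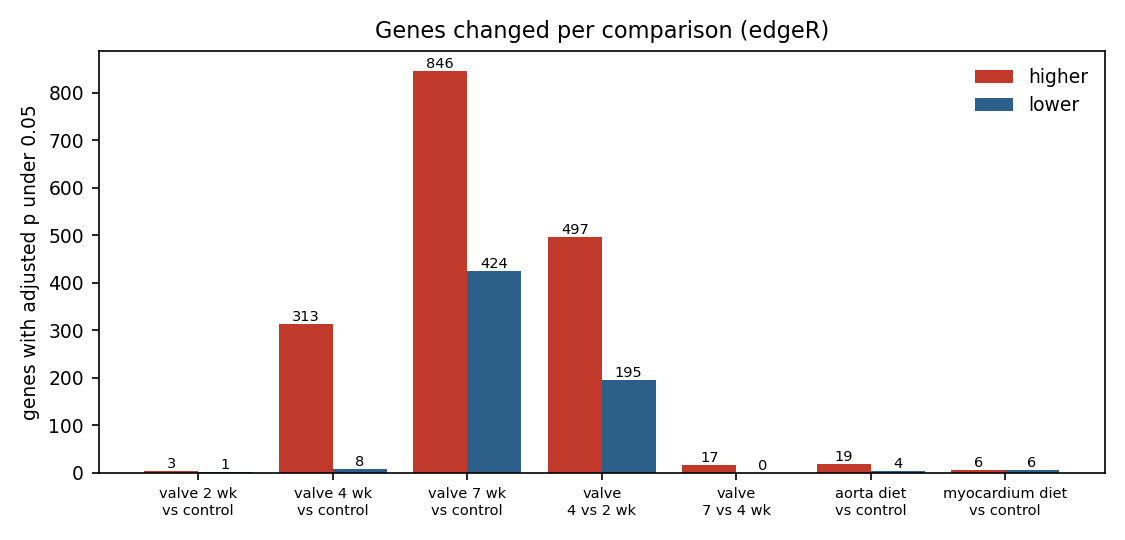
Genes past an adjusted p of 0.05 by edgeR, higher in red and lower in blue, for the 3 diet durations against control valves, between durations, and for diet against control in aorta and myocardium. The 7-week valves had 846 higher and 424 lower genes, the 2-week valves 3 and 1.

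After 4 weeks of diet, macrophage genes rose together in the valves (n = 4 against 4 controls). Of 16 members tested, 13 rose over all genes tested and 15 adjusted over the list alone, with a median of 2.17. MSR1, a scavenger receptor for modified lipoproteins, rose 10.3-fold (3.36 ± 0.57), ITGB2, the leukocyte integrin beta chain, 9.91-fold (3.31 ± 0.59), and CD14, the endotoxin co-receptor, 6.15-fold (2.62 ± 0.47). SPI1, a master transcription factor of myeloid cells, rose by 2.48 ± 0.45, and CD68 rose from 15.6 ± 6.51 CPM (SD) to 65.2 ± 30.2, by 2.06 ± 0.39. The camera adjusted p was 1.05e-29, and adjusted p = 0.0962 with an estimated correlation. ITGAX, the CD11c integrin of myeloid cells, rose by 4.16 ± 0.81 and ATP8B4, a phospholipid flippase, by 2.67 ± 0.42. In 4-week replicate 4 CD68 was at 22.9 CPM, below control replicate 1 at 23.8, against 69.7 to 94.2 in the other 3, and its macrophage score was 4.07 against at most 3.99 in controls. None of the calls over all genes was kept without 4-week replicate 3 or without control replicate 2, 3 or 4, while the median of the list ran from 2.04 to 2.47 over the 8 libraries left out in turn. Without 4-week replicate 3 ITGAX stood at 3.08 ± 0.68 and ITGB2 at 2.65 ± 0.52. Control replicate 1 left out raised ITGAX to 5.05 ± 0.91 and MSR1 to 4.35 ± 0.55.

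Genes of lipid-laden macrophages and proteases rose beside them. In the lipid-laden macrophage list 3 of 14 rose over all genes, and 8 were higher and 1 lower adjusted over the list alone. They were TREM2, a lipid-sensing receptor (3.08 ± 0.55), GPNMB (3.17 ± 0.65) and ATP6V0D2, a subunit of the vacuolar proton pump (3.69 ± 0.71). Of matrix proteases and inhibitors, 4 of 23 rose (10 adjusted over the list alone): MMP9, gelatinase B (4.93 ± 0.95), PLAUR, the urokinase receptor (2.59 ± 0.41), TIMP1, a protease inhibitor (1.81 ± 0.34), and CTSS, cathepsin S (2.02 ± 0.38). Of leukocyte adhesion genes and cytokines, 5 of 21 rose (9 adjusted over the list alone), among them the chemokines CCL2 (2.42 ± 0.49), CCL19 (2.54 ± 0.54) and CXCL8 (3.24 ± 0.78). The complement list had 2 of 13 higher (7 adjusted over the list alone), the anaphylatoxin receptors C3AR1 (2.09 ± 0.33) and C5AR1 (2.45 ± 0.42). The lysosome list had 3 of 31 (10 adjusted over the list alone), with GUSB at 1.22 ± 0.29. The T and B lymphocyte list had 1 of 12 (3 adjusted over the list alone), IL7R, the interleukin 7 receptor (2.37 ± 0.54). For these 6 lists the camera adjusted p was 1.28e-08 to 6.22e-06, and adjusted p = 0.233 with an estimated correlation in each. Here too none of the calls over all genes was kept without 4-week replicate 3 or control replicate 2, 3 or 4. Without 4-week replicate 3, the highest of its group for MMP9, MMP9 stood at 3.24 ± 0.67, ATP6V0D2 at 2.63 ± 0.56, GPNMB at 2.42 ± 0.57 and IL7R at 1.76 ± 0.49. Control replicate 1 left out raised MMP9 to 6.09 ± 1.102 and CXCL8 to 4.84 ± 0.93.

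Cell cycle genes also rose at 4 weeks: 10 of 38 over all genes and 34 adjusted over the list alone, with a median of 1.92. BUB1, a spindle checkpoint kinase, rose by 2.54 ± 0.48, FOXM1, a mitotic transcription factor, by 2.41 ± 0.46, and MCM6, a subunit of the replicative helicase, by 1.54 ± 0.31 (list adjusted p = 2.43e-39 by camera, adjusted p = 0.0962 with an estimated correlation). Other genes that rose were SOCS3, a feedback inhibitor of cytokine signalling (2.04 ± 0.31), TNN, tenascin N (2.89 ± 0.46), TNC, tenascin C (1.93 ± 0.45), the cholesterol exporter ABCG1 (1.80 ± 0.43), JUNB (1.51 ± 0.30), SMAD7 (0.58 ± 0.14) and the mitochondrial carrier UCP2 (2.00 ± 0.38). Of the 8 genes that fell, 4 were named by the rule: FHL2, a LIM-domain protein of muscle (-1.91 ± 0.42), HRH1, the histamine H1 receptor (-1.40 ± 0.30), EPHX2, soluble epoxide hydrolase (-1.37 ± 0.33), and CDK5RAP1 (-0.56 ± 0.14). The calls over all genes were lost in the same 4 fits (without 4-week replicate 3 and control replicates 2, 3 and 4), while the cell cycle median ran from 1.64 to 2.68 over the 8 libraries left out in turn. With control replicate 1 left out TNC stood at 2.54 ± 0.42.

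The muscle genes NPPA, MYL4, SLN and MYH8 rose at 4 weeks, with large folds. NPPA, atrial natriuretic peptide, rose from 1.33 ± 1.09 CPM (SD) to 1002 ± 1539 (9.57 ± 1.72). MYL4 rose by 7.47 ± 1.75, SLN, sarcolipin, by 7.95 ± 1.72, and MYH8, a developmental myosin, by 5.72 ± 1.38. MYL7, the other atrial light chain, did not pass (6.18 ± 1.60, adjusted p = 0.0585). Without 4-week replicate 1, the highest of its group for NPPA, NPPA stood at 7.51 ± 1.38, while MYL4 (5.64 ± 1.503, adjusted p = 0.0945), SLN (6.01 ± 1.46, adjusted p = 0.0669) and MYH8 (4.03 ± 1.198, adjusted p = 0.151) no longer passed. None of the 4, nor NOS3, passed without 4-week replicate 3 or without control replicate 2, 3 or 4. NPPA stood at 10.25 ± 2.07 without control replicate 3 and MYH8 at 6.38 ± 1.68 without control replicate 4. The cardiomyocyte list had 2 of 24 higher over all genes (3 adjusted over the list alone), but a median of -0.85, a mean of 0.25, and a lower rank by camera (adjusted p = 0.0140, adjusted p = 0.635 with an estimated correlation). MYH7, the ventricular myosin, stood at -2.51 ± 0.85. Mesothelial and epithelial genes had a median of 2.21, with 0 of 12 past the threshold and 4 adjusted over the list alone, KRT19 at 2.94 ± 0.77. NOS3, endothelial nitric oxide synthase, passed (6.55 ± 1.55), at 0 to 0.245 CPM in controls and 0.347 to 9.39 at 4 weeks, but it ranged from 0 upward among the libraries of the 2-week valves (0 to 13.3) and of both myocardium groups, so its value is uncertain. Without control replicate 3 it stood at 9.55 ± 2.50.

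Camera further ranked higher at 4 weeks the lists of LXR targets and cholesterol efflux (median 0.29), neutrophil (1.73), mineralisation inhibitors (0.37), extracellular matrix proteins (0.48), TGF-beta response (0.14), unfolded protein (0.27), immediate early genes (0.40) and mesothelial genes. It ranked lower smooth muscle and myofibroblast (-0.39), oxidative phosphorylation (-0.51), fatty acid oxidation (-0.54), adipocyte (-0.61), Schwann cell (-0.45) and endothelial (-0.25, with a mean of 0.08) lists. With list members also matched by gene number, chosen after seeing the data, the Schwann cell list was no longer called (adjusted p = 0.0598). Over all genes tested, 1 member each was higher in the LXR list (ABCG1), the matrix list (TNC), the TGF-beta list (SMAD7), the immediate early list (JUNB), the fatty acid oxidation list (UCP2) and the endothelial list (NOS3). The higher members adjusted over the list alone numbered 2, 3, 3, 5, 1 and 1 in that order, with 1 lower in the TGF-beta and 1 in the endothelial list, 2 in the neutrophil list and 0 in the other lists but the mesothelial. For these 14, adjusted p = 0.233 to 0.607 with an estimated correlation. Genes named whatever their result stood at 0.78 ± 0.42 for ABCA1, 1.305 ± 0.39 for SPP1, 1.305 ± 0.34 for VCAM1, -0.04 ± 0.41 for RUNX2, 1.18 ± 0.38 for ALPL and -0.17 ± 0.28 for BMP2. They stood at 0.21 ± 0.40 for SOX9, 0.37 ± 0.30 for MGP, -0.36 ± 0.31 for ACTA2, 1.299 ± 0.37 for COL1A1 and 1.57 ± 0.81 for IL1B, and none of these 11 passed by edgeR. The test called 321 of 15627 genes, 313 higher and 8 lower, with adjusted p of 0.0188 or more. The count was 158, 50, 0 and 794 without 4-week replicates 1 to 4, and 0 without control replicates 2, 3 and 4; the 4 fits with 0 had 1505, 2085, 1540 and 1787 genes at an unadjusted p under 0.05. DESeq2 called 761 genes and a fit of the 8 libraries alone 2. By edgeR, 0 genes passed with the atrial score as a covariate (2348 at an unadjusted p under 0.05) and 0 with the share of RN18S as a covariate (1013), both chosen after seeing the data.

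**Figure D3:**
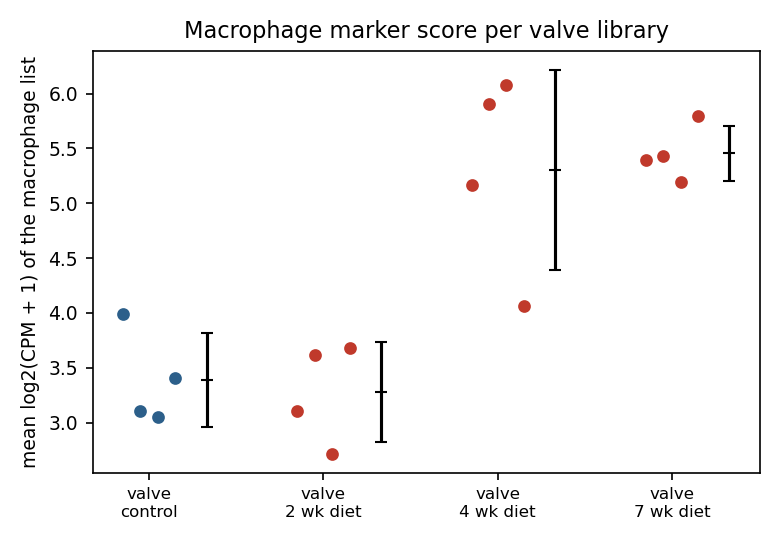
Macrophage marker score, the mean log2 of CPM plus 1 over the genes of the macrophage list, for each of the 16 valve libraries by group; blue points are controls, red points diet, and bars the mean with SD (n = 4). The median log2 fold change of the list was -0.09 at 2 weeks, 2.17 at 4 weeks and 2.39 at 7 weeks.

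After 7 weeks of diet the valves (n = 4 against 4 controls) again had more transcripts of macrophages and of lipid-laden macrophages. In the macrophage list 13 of 16 rose over all genes and 15 adjusted over the list alone, with a median of 2.39. TYROBP, a signalling adaptor of myeloid receptors, rose 8.89-fold (3.15 ± 0.51), AIF1 5.35-fold (2.42 ± 0.39), CD14 7.53-fold (2.91 ± 0.47) and CD68 5.10-fold (2.35 ± 0.40). In the lipid-laden list 7 of 14 rose on both counts, among them TREM2 (3.28 ± 0.56), GPNMB (3.66 ± 0.66), the fatty acid carrier FABP5 (1.76 ± 0.34) and SPP1 (2.02 ± 0.40). In the valve the camera adjusted p was 8.81e-20 and 1.20e-06, and adjusted p = 0.245 for both with an estimated correlation. Among LXR targets, which are induced by sterols, 2 of 10 rose (6 adjusted over the list alone), the cholesterol exporter ABCG1 (2.35 ± 0.44) and the phospholipid transfer protein PLTP (2.09 ± 0.42). In cholesterol biosynthesis, LSS, lanosterol synthase, fell (-0.58 ± 0.16) as the single member of 21 past the threshold on both counts; the median was -0.25. With 7-week replicate 4 left out GPNMB stood at 2.93 ± 0.59.

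Other leukocyte and blood genes rose at 7 weeks. Of the neutrophil list 4 of 6 rose (5 adjusted over the list alone), the chemokine receptors CXCR1 (2.17 ± 0.51) and CXCR2 (2.11 ± 0.52) and the calprotectin genes S100A8 (3.43 ± 0.93) and S100A9 (2.63 ± 0.72). Of the T and B lymphocyte list 3 of 12 rose (7 adjusted over the list alone), including CD79A, a chain of the B cell receptor (2.75 ± 0.53). Red cell genes rose with them, 5 of 6 over all genes and 6 adjusted over the list alone, with a median of 1.71; the alpha globin gene HBA stood at 3836 ± 955 CPM (SD) against 1246 ± 616 in controls (1.62 ± 0.45). Leukocyte adhesion genes and cytokines had 6 of 21 higher (9 adjusted over the list alone), with the adhesion molecules VCAM1 (1.62 ± 0.34) and ICAM1 (1.21 ± 0.25) and the chemokines CCL19 (2.99 ± 0.55) and CX3CL1 (2.42 ± 0.48). Complement had 3 of 13 higher (5 adjusted over the list alone), with C5AR1 at 2.45 ± 0.42, and lysosome 8 of 31 (13 adjusted over the list alone), with CTSH at 0.90 ± 0.21. These 6 lists had camera adjusted p of 8.81e-06 to 0.000208, and adjusted p = 0.245 to 0.343 with an estimated correlation. NOS2, inducible nitric oxide synthase, rose by 2.23 ± 0.30, PTK2B, a focal adhesion kinase, by 1.84 ± 0.25, PRR15 by 3.25 ± 0.37, and IL3RA, the interleukin 3 receptor, by 5.41 ± 1.02. Without 7-week replicate 2, S100A8 (2.12 ± 0.78, adjusted p = 0.132) and S100A9 (2.01 ± 0.68, adjusted p = 0.103) no longer passed. CD79A stood at 3.37 ± 0.56 without control replicate 1 and IL3RA at 6.27 ± 1.22 without control replicate 3.

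Some genes of matrix proteases and their inhibitors rose and contractile genes fell at 7 weeks. Of matrix proteases and inhibitors 8 of 23 rose on both counts, with TIMP1 at 2.53 ± 0.34, PLAUR at 2.96 ± 0.42 and MMP9 at 3.77 ± 0.92 (list adjusted p = 1.57e-05, adjusted p = 0.285 with an estimated correlation). MMP13, collagenase 3, was at 6.86 ± 6.57 CPM (SD) against 0.0586 ± 0.0774 in controls, which had few reads (adjusted p = 0.00597). Of smooth muscle and myofibroblast genes 7 of 16 fell over all genes and 12 adjusted over the list alone, with a median of -1.16. They included the calponin CNN1 (-1.46 ± 0.35), the actin ACTA2 (-1.13 ± 0.31) and MYOCD, a transcriptional co-activator of smooth muscle genes (-1.19 ± 0.29); the camera adjusted p was 1.26e-07, and adjusted p = 0.245 with an estimated correlation. Extracellular matrix proteins went both ways, with 3 higher and 3 lower of 43 (5 and 4 adjusted over the list alone) and camera adjusted p = 0.231: TNC (2.36 ± 0.46) and fibronectin FN1 (1.60 ± 0.37) rose and FBLN5 (-1.30 ± 0.23) fell. The TGF-beta response list had 2 higher and 1 lower of 20 (3 and 2 adjusted over the list alone; median -0.04, mean 0.08, camera adjusted p = 0.869), TGFB1 (1.31 ± 0.27) and TGFB2 (-0.99 ± 0.18) in opposite directions. Cell cycle genes rose, 18 of 38 over all genes and 30 adjusted over the list alone, with BIRC5, survivin, at 1.89 ± 0.33 (adjusted p = 4.97e-18, adjusted p = 0.245 with an estimated correlation). Control replicate 1 left out raised MMP9 to 4.92 ± 1.07 and TNC to 2.96 ± 0.42.

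Genes of bone and cartilage were mixed at 7 weeks. Of the osteogenic and chondrogenic list 6 rose and 2 fell of 30 over all genes (8 and 3 adjusted over the list alone), and camera gave adjusted p = 0.107. ACAN, aggrecan, rose by 1.69 ± 0.37, DLX3, a homeobox factor, by 2.74 ± 0.63 and ALPL by 1.38 ± 0.38, while BGLAP, osteocalcin, fell (-2.52 ± 0.52). TNFSF11, the RANK ligand, passed (adjusted p = 0.0132) at 1.99 ± 1.72 CPM (SD) against 0.0758 ± 0.101 in controls, which had few reads. Of mineralisation inhibitors 4 rose and 2 fell of 15 on both counts (camera adjusted p = 0.235), with ANKH, a pyrophosphate transporter, at 0.98 ± 0.21, SOST, sclerostin, at -2.17 ± 0.45 and KL, klotho, at -3.20 ± 0.70. Of vitamin D response genes 2 of 10 rose (4 adjusted over the list alone), CDKN1A (1.38 ± 0.32) and IGFBP3 (2.06 ± 0.56), with VDR at 1.12 ± 0.41 (list adjusted p = 0.0440, adjusted p = 0.285 with an estimated correlation). In the NRF2 list 4 of 18 rose over all genes (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.107), among them heme oxygenase HMOX1 (2.05 ± 0.38) and the ferritins FTL (1.41 ± 0.29) and FTH1 (1.02 ± 0.21). Genes outside the lists that fell were OSR1, a developmental transcription factor (-2.17 ± 0.36), BMP3 (-2.19 ± 0.47), HRH1 (-1.89 ± 0.31), RARB, a retinoic acid receptor (-1.24 ± 0.20), PDZD2 (-1.56 ± 0.26), PDLIM3 (-1.05 ± 0.17), FAIM2 (-2.11 ± 0.58) and NIPAL4 (-2.07 ± 0.57). LEP, the adipocyte hormone leptin, fell too (-3.12 ± 0.67). DLX3 no longer passed without 7-week replicate 4 (2.08 ± 0.61, adjusted p = 0.0712), nor KL without control replicate 2 (-2.49 ± 0.64, adjusted p = 0.0508). Control replicate 1 left out raised DLX3 to 3.39 ± 0.72 and IGFBP3 to 2.95 ± 0.51.

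Some genes of heart muscle and of covering epithelia also rose at 7 weeks. NPPA rose from 1.33 ± 1.09 CPM (SD) to 1058 ± 878 (9.65 ± 1.73), MYL4 by 7.09 ± 1.72, MYL7 by 5.60 ± 1.56, SLN by 7.45 ± 1.70 and MYBPHL by 4.98 ± 1.47, while MYH7 stood at -0.17 ± 0.81. Without 7-week replicate 3 MYL4 stood at 5.78 ± 1.58 and SLN at 6.68 ± 1.69, and MYL7 (4.30 ± 1.46, adjusted p = 0.0934) and MYBPHL (3.70 ± 1.41, adjusted p = 0.130) no longer passed. MYL7 did not pass without control replicate 4 either (6.26 ± 1.87, adjusted p = 0.0663), and NPPA stood at 10.31 ± 2.07 without control replicate 3. The cardiomyocyte list had 3 of 24 higher on both counts, a median of 0.25 and camera adjusted p = 0.154. Mesothelial and epithelial genes had 3 of 12 higher (6 adjusted over the list alone), with the keratin KRT19 at 3.01 ± 0.77, not past the threshold without 7-week replicate 3 (2.24 ± 0.72, adjusted p = 0.0801) and 3.62 ± 0.87 without control replicate 2 (list adjusted p = 0.000194, adjusted p = 0.285 with an estimated correlation). Endothelial genes had 2 higher and 1 lower of 20 (5 and 1 adjusted over the list alone), with VWF, von Willebrand factor, at 1.34 ± 0.37, ESAM at -0.52 ± 0.14 and NOS3, uncertain as at 4 weeks, the other higher member. The lists of NOTCH and WNT signalling (median -0.23, 2 of 28 lower, with HEY2 at -1.39 ± 0.26), interferon response (-0.54, 1 of 16 lower, IFIT2 at -0.99 ± 0.27) and Schwann cell genes (-0.47, 1 of 14 lower, NCAM1 at -0.69 ± 0.17) ranked lower by camera, and immediate early genes (0.54, 3 of 21 higher, JUNB at 1.53 ± 0.30) ranked higher. Adjusted over the list alone, 4, 1 and 1 genes were lower in the first 3 of these, and 7 higher and 1 lower in the last. For these lists, the endothelial, LXR and cholesterol biosynthesis lists included, adjusted p = 0.275 to 0.556 with an estimated correlation. Interferon response and Schwann cell genes were no longer called with list members also matched by gene number, chosen after seeing the data (adjusted p = 0.0628 and 0.105).

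Lists without a call by camera at 7 weeks were oxidative phosphorylation (median 0.20), fatty acid oxidation (-0.16), hypoxia and glycolysis (0.23), unfolded protein and integrated stress response (0.14), valve interstitial and fibroblast (-0.30), adipocyte (-0.50) and melanocyte (-0.09, with a mean of 1.09). Of these, on both counts, 1 fatty acid oxidation, 1 unfolded protein and 1 melanocyte gene were higher, 2 valve interstitial genes and 1 adipocyte gene lower, and hypoxia had 1 each way. Oxidative phosphorylation turned to a median of -0.28 (adjusted p = 0.000266) with the cardiomyocyte score as a covariate and to -0.58 (adjusted p = 7.07e-06) with the atrial score. Genes named whatever their result that did not pass by edgeR stood at 1.03 ± 0.42 for ABCA1, 0.74 ± 0.41 for RUNX2, 0.48 ± 0.28 for BMP2, -0.38 ± 0.41 for SOX9, 0.66 ± 0.30 for MGP, 0.87 ± 0.36 for COL1A1 and 2.06 ± 0.80 for IL1B. The test called 1270 of 15627 genes, 846 higher and 424 lower, with adjusted p from 0.00287, and DESeq2 called 2231. The count was 2283, 843 and 533 without 7-week replicates 1, 2 and 4, and 477, 460 and 722 without control replicates 2, 3 and 4. With an erythroid or an atrial score as a covariate, both chosen after seeing the data, 0 genes passed (2599 and 2280 at an unadjusted p under 0.05).

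**Figure D4:**
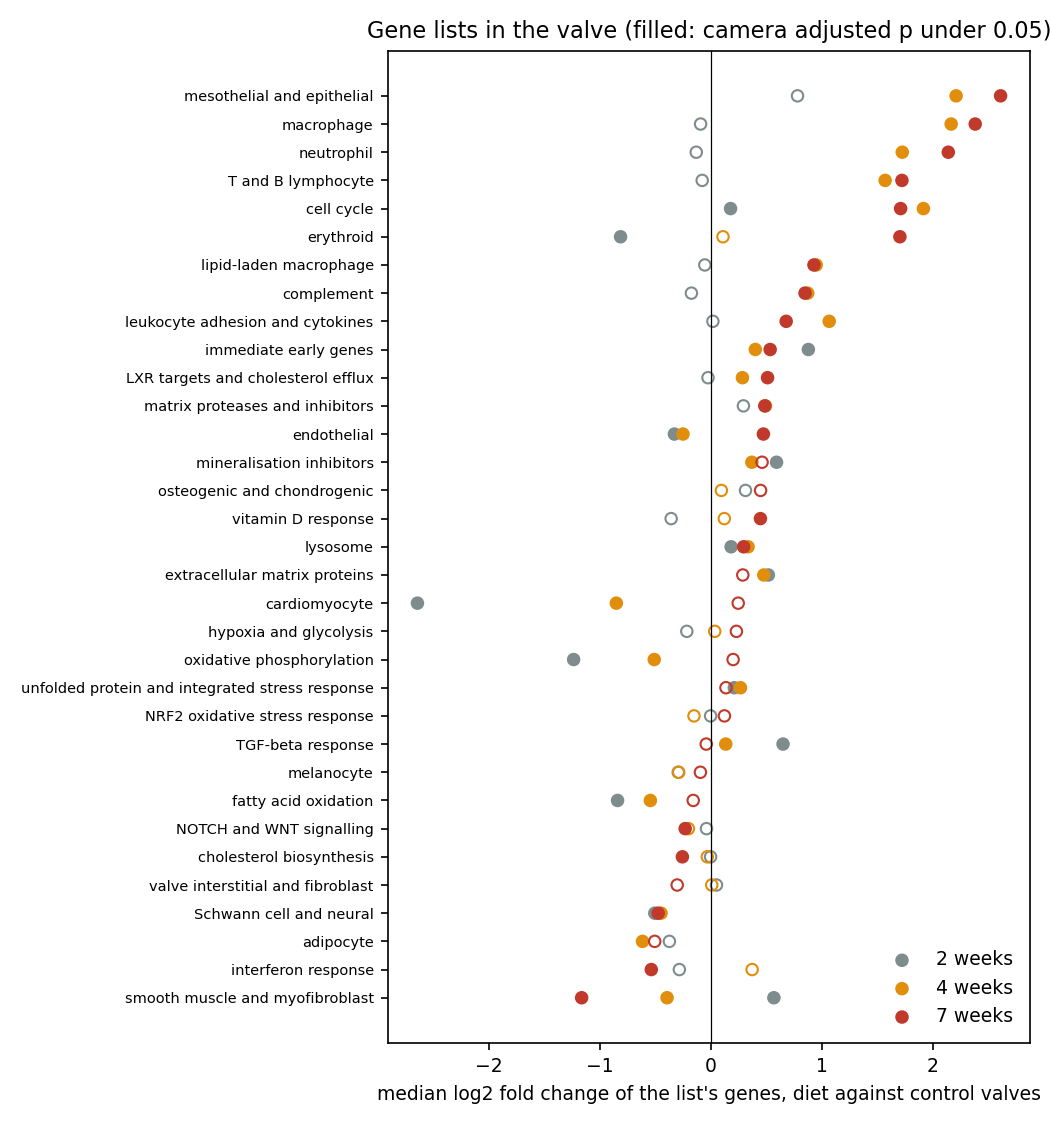
Median log2 fold change of each gene list, diet against control valves, at 2 weeks (grey), 4 weeks (orange) and 7 weeks (red); filled points passed camera at an adjusted p of 0.05 with the preset correlation. The macrophage list was at -0.09, 2.17 and 2.39, and the smooth muscle and myofibroblast list at 0.57, -0.39 and -1.16.

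Between 2 and 4 weeks of diet the valves differed in macrophage, cell cycle, TGF-beta and contractile genes. Macrophage genes rose, 14 of 16 over all genes and 15 adjusted over the list alone, with LAPTM5 at 2.50 ± 0.38 and AIF1 at 2.36 ± 0.39. Cell cycle genes rose, 14 of 38 (33 adjusted over the list alone), with FOXM1 at 2.32 ± 0.45. The proteases MMP12 (6.90 ± 1.38) and MMP9 (6.47 ± 1.06), ITGAX (5.09 ± 0.85) and CLEC5A, a myeloid lectin (4.35 ± 0.69), rose; without 4-week replicate 3 they stood at 5.67 ± 1.23, 4.79 ± 0.74, 4.01 ± 0.71 and 3.51 ± 0.58, in this order. TGF-beta response genes fell, 3 of 20 (11 adjusted over the list alone), with BAMBI at -1.65 ± 0.29, as did the smooth muscle list, 2 of 16 (14 lower and 1 higher adjusted over the list alone), with ACTA2 at -1.16 ± 0.31. The elastic fibre genes FBLN5 (-1.07 ± 0.23) and ELN (-1.53 ± 0.39) fell, and so did HRH1 (-2.10 ± 0.31), ADAMTS9 (-1.97 ± 0.49), EGR1 (-1.80 ± 0.49) and RANBP3L (-1.69 ± 0.39). RN18S, the 18S ribosomal RNA, whose share of a library also depends on how RNA is prepared, fell (-2.27 ± 0.52), from 1.65% of counts (1.36 to 1.97) at 2 weeks to 0.370% (0.282 to 0.516) at 4 weeks. Heart muscle genes moved too: NPPA (5.39 ± 1.40) and MYH8 (4.98 ± 1.27) rose. Without 4-week replicate 1 NPPA (3.33 ± 1.12, adjusted p = 0.161) and MYH8 (3.30 ± 1.103, adjusted p = 0.159) no longer passed, nor did EGR1 without 2-week replicate 3 (-0.80 ± 0.28, adjusted p = 0.182). The cardiomyocyte list had 1 of 24 higher (11 adjusted over the list alone) with a median of 1.98, and oxidative phosphorylation a median of 0.73, with 1 of 38 higher (0 adjusted over the list alone). With the cardiomyocyte score as a covariate the direction of oxidative phosphorylation reversed, to a median of -0.23 (adjusted p = 0.00556). For these 6 lists the camera adjusted p was 8.47e-24 to 9.37e-07, and adjusted p = 0.222 to 0.539 with an estimated correlation. Camera also ranked 11 further lists higher, from leukocyte adhesion (median 1.02) to erythroid genes (1.07), and for these adjusted p = 0.278 to 0.551 with an estimated correlation. The test called 692 of 15627 genes, 497 higher and 195 lower. The count was 336, 291, 354 and 1248 without 4-week replicates 1 to 4, 242 and 220 without 2-week replicates 1 and 3, and 390 with the cardiomyocyte score as a covariate. With the share of RN18S as a covariate, chosen after seeing the data, edgeR called 0 genes (2272 at an unadjusted p under 0.05; DESeq2 without the covariate called 1482). The shares of the 2 groups do not overlap, so a loss of calls was to be expected. The macrophage median went from 2.40 to 1.56 as its median SE rose from 0.46 to 0.76, and that of the cell cycle from 1.60 to 0.46 as its SE rose from 0.47 to 0.71. The 7-week valves, at 1.58% RN18S, had a mean macrophage score of 5.45 (5.197 to 5.79) against 3.28 (2.72 to 3.68) at 2 weeks, so a low share is not needed for a high score.

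Between 4 and 7 weeks, 17 genes rose and 0 fell by edgeR, and each of the 17 has a LOC number in place of a symbol. Endothelial genes stood higher as a set at 7 weeks, with a median of 0.72 and 12 of 20 passing adjusted over the list alone (0 over all genes), CLDN5, a tight junction gene, at 0.75 ± 0.21. All 6 erythroid genes passed adjusted over the list alone (0 over all genes), with a median of 1.59 and SLC4A1, the red cell anion exchanger, at 2.30 ± 0.56. Oxidative phosphorylation (median 0.63), fatty acid oxidation (0.38), cardiomyocyte (1.00), neutrophil (0.98) and vitamin D response (0.33) genes ranked higher by camera. Interferon response (-0.80), smooth muscle (-0.67), extracellular matrix (-0.24) and valve interstitial (-0.17) genes ranked lower, with FBLN5 at -1.19 ± 0.23. The camera adjusted p was 5.85e-11 to 0.0498 for these 11, and adjusted p = 0.332 to 0.629 with an estimated correlation. The macrophage list had a median of -0.05, a mean of -0.03 and an upward rank by camera (adjusted p = 0.440), between groups whose sequencing numbers lie apart. At an unadjusted p under 0.05 there were 1880 genes, and DESeq2 called 196. The count was 54 and 9 without 7-week replicates 1 and 3, 5, 10 and 4 without 4-week replicates 1, 2 and 4, and 0 with the erythroid score or the share of RN18S as a covariate, both chosen after seeing the data (1017 and 941 at an unadjusted p under 0.05).

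The valve response at 4 weeks resembled that at 7 weeks. Of the 313 genes that rose at 4 weeks, 291 also rose at 7 weeks, where independent lists of these sizes would share 16.9, and 3 of 8 that fell also fell, against 0.217. The 2 comparisons share the controls, so the lists are not independent. In 20 sets of unchanged groups simulated against them, at most 1 gene rose and 0 were shared. With no control library in common, 0 genes were shared in each of 6 splits. Calls of higher genes fell to at most 261 at 4 weeks and 583 at 7 weeks, and no split had more than 2 at both times. With so few calls, neither test shows how much the controls add. Across 15627 genes, which are not independent replicates, log2 fold changes at 4 and 7 weeks correlated with r = 0.735, at 2 and 4 weeks with r = 0.346 and at 2 and 7 weeks with r = 0.118. Unchanged groups simulated against the same controls gave a mean r of 0.500, 0.504 and 0.503. The covariance exceeded that of unchanged groups by 0.345 for 4 and 7 weeks and by 0.0804 for 2 and 4 weeks, and differed from it by -0.0161 for 2 and 7 weeks. With the controls split so that no library was shared, r was 0.467, 0.142 and -0.00615 on average over 6 splits, in the same order. Each comparison then had 2 controls in place of 4, and the covariance was 0.392 in place of 0.424 for 4 and 7 weeks.

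In the ascending aorta, 2 diet libraries were compared with 3 controls, and heart muscle genes rose. MYH6, the alpha myosin heavy chain, rose by 9.77 ± 0.22. MYL4 rose from 0.685 ± 0.275 CPM (SD) to 82.4 ± 5.22 (6.85 ± 0.24). MYL7 passed (adjusted p = 0.0111) at 14.1 ± 0.393 CPM (SD) against 0.0274 ± 0.0475 in controls, which had few reads. ACTC1, cardiac actin (1.99 ± 0.19), UNC45B, a myosin chaperone of striated muscle (4.11 ± 0.34), PGAM2, the muscle phosphoglycerate mutase (3.15 ± 0.21), and DSP, desmoplakin (2.25 ± 0.21), rose with them, while MYH7 stood at -1.48 ± 0.48. The cardiomyocyte list had 4 of 24 higher over all genes, and 14 higher and 6 lower adjusted over the list alone (adjusted p = 4.38e-31, adjusted p = 0.283 with an estimated correlation). NEFM, a neurofilament (5.10 ± 0.35), CREB5, a transcription factor (2.17 ± 0.16), KLF10 (1.69 ± 0.13) and TRAF3, a signalling adaptor (1.37 ± 0.12), rose, and ITGA11, a collagen-binding integrin, fell (-2.57 ± 0.20). Camera ranked lower cholesterol biosynthesis (median -0.51), lipid-laden macrophage (-0.49), endothelial (-0.61) and adipocyte (-1.13) genes, and ranked higher smooth muscle (0.24) and extracellular matrix (0.24) genes. In these 6 lists 0 genes passed over all genes; adjusted over the list alone, 1 smooth muscle gene was higher and, of the matrix list, 1 was higher and 1 lower. The camera adjusted p of the 6 was 0.00525 to 0.0175, and each had adjusted p = 0.737 with an estimated correlation. The macrophage list had a median of -0.04.

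Of the genes named whatever their result, MMP9 and IL1B were too low to be tested in the aorta, and the other values were 0.58 ± 0.23 for ABCA1, -1.13 ± 0.94 for SPP1, -0.19 ± 0.22 for CD68, 0.08 ± 0.38 for VCAM1 and -1.82 ± 0.93 for RUNX2. They were -0.53 ± 0.40 for ALPL, -0.04 ± 0.26 for BMP2, 0.16 ± 0.45 for SOX9, -0.72 ± 0.17 for MGP, -0.01 ± 0.19 for ACTA2 and 0.58 ± 0.22 for COL1A1, and none of these 11 passed by edgeR. The test called 23 of 14435 genes, 19 higher and 4 lower, and DESeq2 called 408. The count was 2 and 3 without diet replicates 1 and 2, which leaves a single diet library assumed to vary like the controls, and 3, 284 and 40 without control replicates 1 to 3.

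In the left ventricular myocardium (n = 3 diet against 3 controls), IGFBP3, an insulin-like growth factor binding protein that is also on the vitamin D response list, rose 11.0-fold (3.46 ± 0.35), and LRP2, the endocytic receptor megalin, rose 17.2-fold (4.10 ± 0.42). DNASE1 (-3.07 ± 0.35) and PDGFRL, a receptor-like protein (-1.71 ± 0.21), fell. In each of the 4, the 3 diet libraries lay outside the range of the 3 controls. Atrial genes and MYH6, chosen after seeing the data, did not pass: NPPA (7.09 ± 1.24, adjusted p = 0.107), MYL4 (3.73 ± 1.05, adjusted p = 0.293), MYL7 (0.67 ± 0.90, adjusted p = 0.938) and MYH6 (-3.06 ± 0.88, adjusted p = 0.302). Macrophage genes had a median of 0.79, with 0 of 15 past the threshold over all genes and 3 adjusted over the list alone, MRC1, the mannose receptor, at 1.84 ± 0.43. GPNMB stood at 5.05 ± 0.65, adjusted p = 0.0544, and 3 of 12 lipid-laden macrophage genes were higher adjusted over the list alone. TGF-beta response genes had 5 higher and 1 lower of 20 adjusted over the list alone, and immediate early genes 6 higher of 18, with IER3 at 1.42 ± 0.28. LXR targets had 3 higher of 10 adjusted over the list alone, with ABCA1 at 1.07 ± 0.27, and interferon response genes 4 lower of 16. Over all genes 0 members of these 6 lists passed. Of the vitamin D response list 1 of 9 rose (2 adjusted over the list alone). Camera also ranked higher neutrophil (1.16), fatty acid oxidation (0.26) and complement (0.45) genes and ranked lower endothelial genes (-0.48). For these 11 lists the camera adjusted p was 5.36e-09 to 0.0229, and adjusted p = 0.179 to 0.897 with an estimated correlation.

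Of the genes named whatever their result, MMP9 and IL1B were too low to be tested in the myocardium. SPP1 stood at 3.05 ± 0.78, CD68 at 0.61 ± 0.33, VCAM1 at 0.49 ± 0.40, RUNX2 at -0.28 ± 0.50 and ALPL at -0.02 ± 0.39. BMP2 stood at -0.61 ± 0.44, SOX9 at 1.92 ± 0.46, MGP at -0.30 ± 0.39, ACTA2 at -0.69 ± 0.58, COL1A1 at -0.29 ± 0.30 and MYH7 at 0.27 ± 0.42, and none of these 11, nor ABCA1, passed by edgeR. The test called 12 of 14151 genes, 6 higher and 6 lower, 8 of them with LOC numbers; DESeq2 called 308. The count was 1, 6 and 4 without diet replicates 1 to 3, 36 and 6 without control replicates 1 and 2, and 76 without the low-count filter.

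The diet effect of the 7-week valve (n = 4 and 4) was compared with that of the myocardium (n = 3 and 3); 5 animals gave both tissues. It was higher in the valve for NOS2 (3.61 ± 0.49, difference of log2 fold changes), the chemokine CX3CL1 (3.84 ± 0.74), POU2F2, a B cell transcription factor (3.47 ± 0.72), ARHGAP22 (3.18 ± 0.55), PRSS53 (4.32 ± 0.81) and CLEC11A, a growth factor of bone (2.84 ± 0.54). It was lower in the valve for DGKG, a diacylglycerol kinase (-3.74 ± 0.78), OSR1 (-3.30 ± 0.75), MAPK4 (-2.89 ± 0.66), IGSF9B (-2.72 ± 0.49), MAFF (-2.49 ± 0.44) and the protease ADAMTS8 (-2.46 ± 0.35). Macrophage genes had a median difference of 1.82, with 0 of 16 past the threshold and 7 adjusted over the list alone, and cell cycle genes 2.38, with 0 of 38 and 24 adjusted over the list alone. Lymphocyte (2.24), leukocyte adhesion (1.25), endothelial (0.89) and erythroid (2.04) genes ranked higher by camera, and TGF-beta response (-0.53) and smooth muscle (-0.74) genes lower; 1 leukocyte adhesion gene was higher over all genes and 1 TGF-beta response gene lower. For the 8 lists the camera adjusted p was 4.43e-19 to 0.00998, and adjusted p = 0.516 to 0.529 with an estimated correlation. Matrix genes went both ways, 3 higher and 2 lower of 43 (11 and 5 adjusted over the list alone), with SPARC, osteonectin, at 2.30 ± 0.46 and the microfibril gene MFAP5 at -1.66 ± 0.32. The test called 108 of 16235 genes, 70 higher and 38 lower, and DESeq2 called 512. The count was 54 and 46 without valve diet replicates 3 and 4, 27, 31 and 60 without valve control replicates 2 to 4, 179 and 21 without myocardium control replicates 1 and 3, and 23 and 5 without myocardium diet replicates 2 and 3. In the 10 libraries of the animals that gave both tissues, with the animal as a block, chosen after seeing the data, edgeR called 0 genes (1525 at an unadjusted p under 0.05) and camera 15 lists, the 8 above among them. The same 10 libraries without the block also gave 0 genes (1390) and 18 lists. Of the genes named here, CX3CL1 (3.16 ± 0.71), POU2F2 (2.82 ± 0.72) and PRSS53 (3.36 ± 0.85) no longer passed without myocardium control replicate 3 (adjusted p = 0.0862, 0.113 and 0.111). DGKG (-3.14 ± 0.76, adjusted p = 0.0560) did not pass without myocardium diet replicate 1, nor MAPK4 (-2.18 ± 0.66, adjusted p = 0.192) without replicate 2. DGKG stood at -4.59 ± 0.81 without myocardium control replicate 2 and POU2F2 at 4.12 ± 0.67 without valve control replicate 1.

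The diet effect of the valve, averaged over the 3 durations (n = 12 diet and 4 control), was compared with that of the aorta (n = 2 and 3). Of the diet aortas, 1 came from a 2-week animal and the duration of the other is not given, so tissue and duration cannot be told apart. It was higher in the valve for ITGA11 (2.40 ± 0.35) and CROT, a peroxisomal carnitine transferase (2.08 ± 0.36), and lower for CREB5 (-3.01 ± 0.46), TGFB2 (-1.64 ± 0.26) and the phosphatase DUSP16 (-1.46 ± 0.26), the other 3 of the 8 genes past the threshold having LOC numbers. Macrophage genes had a median difference of 1.40, positive in all 16, with 0 past the threshold on either count. Lipid-laden macrophage genes had 0.87, with 0 of 14 and 4 adjusted over the list alone. Osteogenic and chondrogenic genes had 0.41, with 0 of 31 and 2 adjusted over the list alone, ACAN at 2.51 ± 0.80. Cardiomyocyte genes had -1.53, with 0 of 24 and 2 lower adjusted over the list alone. Camera called 16 lists, of which these 4 had camera adjusted p of 3.09e-09 to 0.00314, and adjusted p = 0.459 to 0.812 over the 16 with an estimated correlation. The test called 8 of 16542 genes (1518 at an unadjusted p under 0.05) and DESeq2 82. The count moved by more than 1.5 times, to 0 to 5, without each of the 21 libraries in turn except 2-week replicate 1, 4-week replicates 2 and 4 and 7-week replicate 1; it was 0 without control valve replicates 1, 3 and 4 (1591, 1105 and 1550 at an unadjusted p under 0.05) and without either diet aorta (817 and 847), and 1 without control valve replicate 2 and control aorta replicate 3.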

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

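The tests of explanations and the splits of libraries in this part were chosen after the results they bear on had been seen, and the covariates for atrial genes, erythroid genes and the share of RN18S were added after seeing the data.

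Among 108 groups of 4 valve libraries, 1 library lay far from the other 3 in 11, where chance flags about 1 in 20 groups, or 5.4. For genes with at least 10 reads these were 7-week replicate 2 (13881, the lowest) and 4-week replicate 2 (14770, the lowest). For heart muscle genes they were 4-week replicate 1 for NPPA (3289 CPM), 2-week replicate 2 for MYL4 (369.8 CPM) and MYH6 (1847 CPM), 7-week replicate 3 for MYH6 (5419.7 CPM) and control replicate 3 for MYH6 (944 CPM), each the highest of its group. The others, also the highest, were control replicate 1 for VCAM1 (55.3 CPM), 2-week replicate 3 for FOS (753 CPM), 4-week replicate 3 for MMP9 (128 CPM) and control replicate 3 for NOS3 (0.245 CPM).

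Between 4 and 2 weeks of diet, 692 genes differed by a test of the difference, including MMP12 (6.90), MMP9 (6.47), NPPA (5.39), ITGAX (5.09), MYH8 (4.98), CLEC5A (4.35), RN18S (-2.27), HRH1 (-2.10), ADAMTS9 (-1.97), EGR1 (-1.80) and RANBP3L (-1.69). Without 4-week replicate 3, MMP12 stood at 5.67, MMP9 at 4.79, ITGAX at 4.01 and CLEC5A at 3.51, and NPPA (3.33) and MYH8 (3.30) no longer passed without 4-week replicate 1, nor EGR1 (-0.80) without 2-week replicate 3. Chance can be excluded for this count, since the highest of the other 34 splits of the 8 libraries called 16. With the share of RN18S as a covariate edgeR called 0 (2272 at an unadjusted p under 0.05; DESeq2 without it 1482), which decides nothing, since the shares of the 2 groups do not overlap. Between 7 and 4 weeks 17 genes differed, and chance stays open. A split that exchanged replicate 1 of both groups called 2068, which points to a structure other than the duration. The exchange sorts libraries by heart muscle: 2.07% to 5.23% of counts against 0.324% to 1.82%. Also, 4-week replicate 1 has sequencing number 21, its group 36 to 38. Against control valves, chance is as unlikely at 7 weeks (1270 genes, highest other split 3). It stays open at 2 weeks (4 genes, highest other 2, too close) and at 4 weeks (321 genes). At 4 weeks the split that exchanged 4-week replicate 4 and control replicate 1 called 406. In the myocardium (12 genes, highest other 2) the 10 splits are too few for a share under 0.05.

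The diet effect differed between the 7-week valve and the myocardium for 108 genes by a test of the difference, among them PRSS53 (4.32), CX3CL1 (3.84), NOS2 (3.61), POU2F2 (3.47), ARHGAP22 (3.18), CLEC11A (2.84), DGKG (-3.74), OSR1 (-3.30), MAPK4 (-2.89), IGSF9B (-2.72), MAFF (-2.49) and ADAMTS8 (-2.46). Without single libraries, PRSS53 (3.36), CX3CL1 (3.16) and POU2F2 (2.82; myocardium control replicate 3), DGKG (-3.14; myocardium diet replicate 1) and MAPK4 (-2.18; myocardium diet replicate 2) no longer passed. POU2F2 stood at 4.12 without valve control replicate 1 and DGKG at -4.59 without myocardium control replicate 2. Of 100 splits of the libraries within tissues, 2 called as many, the real one included, with a highest other count of 212. These splits separate libraries of the same animal. Of 30 splits that kept animals whole, only the real one called as many (highest other 1). The split that called 212 leaves chance open. Between valve and aorta 8 genes differed by a test of the difference, ITGA11 (2.40), CROT (2.08), CREB5 (-3.01), TGFB2 (-1.64) and DUSP16 (-1.46) among them, with 2 diet aortas and no count of splits.

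The 346 genes that the authors took out of the valve table were tested in the table that holds them. Of these, 1 passed at 4 weeks, LOC100341515 (-5.81 ± 1.36), chosen after its value was seen, and 9 passed at 7 weeks and 9 between 2 and 4 weeks. With symbols, those at 7 weeks were DDN, a cytoskeletal protein (4.99 ± 1.29), PRND, a prion-like protein (5.16 ± 1.24), EFNB3, an ephrin (-2.65 ± 0.69), and MS4A15 (-6.43 ± 1.56). Between 2 and 4 weeks they were CDHR1 (4.01 ± 1.01), DPYSL5 (3.19 ± 0.80), LSMEM1 (3.11 ± 0.68), SLC1A2, a glutamate transporter (2.43 ± 0.59), and the cell cycle factor E2F8 (2.15 ± 0.56).

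Macrophage genes stood higher in the valve at 4 and 7 weeks, with medians of 2.17 and 2.39. With the atrial score as a covariate the medians were 2.46 and 2.58. The calls over all genes went from 13 of 16 to 0 at both times, and 15 of 16 passed adjusted over the list alone. The median SE rose from 0.46 to 0.68 and 0.75. At both times the atrial genes lie above all controls, so this cannot decide on atrial muscle in the cusps. Blood in the tissue as the whole cause is argued against by an erythroid median of 0.11 at 4 weeks, and at 7 weeks by a macrophage median of 2.59 with the erythroid score as a covariate, where the calls over all genes went from 13 to 0 as the median SE rose to 0.73 and 12 of 16 passed adjusted over the list alone. If the 7-week libraries had a run of their own, run and group cannot be told apart. The macrophage median between 4 and 7 weeks was -0.0450. A difference in RNA or library preparation, seen in the share of RN18S, is argued against as the whole cause. With that share as a covariate the median was 2.59 at 7 weeks, with 14 of 16 past the threshold over all genes, and 1.71 at 4 weeks. At 4 weeks the calls over all genes went from 13 to 0, and 12 of 16 passed adjusted over the list alone. The median fell from 2.17 as the median SE rose from 0.46 to 0.61. A part of the 4-week change stays open. More macrophages in the diet valves, or more of these transcripts per macrophage, may explain the change, and these data do not separate them.

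Oxidative phosphorylation genes stood lower in the valve at 2 weeks, with a median of -1.24. Less heart muscle in the 2-week cusps is a candidate explanation: with the cardiomyocyte score as a covariate the median was -0.24, where the median SE was 0.25. An effect of the diet on mitochondrial genes of valve cells stays open, as untested.

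The atrial genes MYL4, NPPA and SLN were higher in the valve at 4 and 7 weeks, and MYL4 and MYL7 in the diet aortas. Without 4-week replicate 1, MYL4 (5.64) and SLN (6.01) no longer passed at 4 weeks. Their switching on by the diet in left ventricular muscle is argued against as the whole cause in the valve, since the highest ratio of MYL4 to the titin gene TTN in diet myocardium was 0.00263, while the median in 12 diet valves was 0.602 (0.00361 to 2.62) and the highest in control valves 0.00807. For NPPA the highest in diet myocardium was 0.00900 and the median in diet valves 0.499, for SLN 0.000545 and 0.0414, and for MYL7 0.000297 and 0.101. In the diet myocardium NPPA stood at 7.09 ± 1.24 (adjusted p = 0.107), MYL4 at 3.73 ± 1.05 and MYL7 at 0.67 ± 0.90. Ratios to TTN were at least 0.000542 for NPPA (controls at most 7.98e-05) and 5.66e-05 for SLN (4.10e-05). MYH6 (232 to 3092 CPM in controls) stood at -3.06 ± 0.88. A part of the NPPA and SLN changes from the diet in muscle stays open, and no other heart muscle was sampled. In the aorta, 8 of 8 genes shared by all heart muscle were higher in both diet libraries than in the 3 controls and 3 of 3 ventricular genes lower, so heart muscle of a non-ventricular kind in the diet samples may explain the aortic change. Whether dissection placed more atrial tissue in diet samples or the diet changed the muscle next to the cusps was not tested.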

How the results depend on the processing

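The covariates for erythroid and atrial genes, the fit without the 2 libraries with the most MYH6, the fit without the 7-week group, the share of RN18S as a covariate, the animal block, list members also matched by gene number and presence as kept by filterByExpr were chosen after seeing the data; the other alternatives were fixed before. Over all alternatives and the libraries left out, values of named genes kept their direction and their side of the threshold in 11014 of 12975, were no longer past it in 1590, newly past it in 369 and reversed in 2. For gene lists the numbers were 4680 of 5318, 421, 194 and 23. RLE size factors, a mean of at least 1 CPM, list members also matched by gene number and the valve counts before the removal of myocardial genes left each count of genes and lists within 1.5 times.

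DESeq2 called 911 genes at 2 weeks, 761 at 4 weeks, 2231 at 7 weeks, 1482 between 2 and 4 weeks, 196 between 4 and 7 weeks, 408 in the aorta, 308 in the myocardium, 512 for valve against myocardium and 82 for valve against aorta. Without the low-count filter the myocardium had 76. With the replicate number as a block the counts were 0 at 2 weeks (2016 at an unadjusted p under 0.05), 5 at 4 weeks, 685 at 7 weeks, 292 between 2 and 4 weeks, 10 between 4 and 7 weeks and 96 in the aorta. The replicate numbers do not pair libraries: correlations of residuals between libraries of the same number ran from -0.339 to 0.124 in valve, -0.0786 to -0.0106 in aorta and -0.225 to 0.0235 in myocardium. For valve against myocardium, the 10 libraries of animals with both tissues gave 0 genes with the animal as a block (1525 at an unadjusted p under 0.05) and 0 without it (1390), with 15 and 18 lists in place of 8.

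In fits of only the groups compared the counts were 397 at 2 weeks, 2 at 4 weeks, 207 between 2 and 4 weeks and 2 between 4 and 7 weeks. Without the 7-week group they were 159 at 2 weeks and 128 at 4 weeks. With the cardiomyocyte score as a covariate they were 0 at 2 weeks (860 at an unadjusted p under 0.05) and 390 between 2 and 4 weeks, and with the adipocyte score 0 at 2 weeks (1904) and 136 at 4 weeks. With the erythroid score they were 0 at 2 weeks (1667), 0 at 7 weeks (2599), 268 between 2 and 4 weeks and 0 between 4 and 7 weeks (1017), with 7 gene lists in place of 11 between 4 and 7 weeks. With the atrial score they were 926 at 2 weeks, 0 at 4 weeks (2348), 0 at 7 weeks (2280) and 225 between 2 and 4 weeks. With the share of RN18S they were 539 at 2 weeks, 0 at 4 weeks (1013), 0 between 2 and 4 weeks (2272) and 0 between 4 and 7 weeks (941). Without the 2 libraries with the most MYH6 they were 0 at 4 weeks (1835), 258 between 2 and 4 weeks and 0 between 4 and 7 weeks (2431). Numbers in brackets are genes at an unadjusted p under 0.05 by edgeR, and DESeq2's counts are above. The cause was not tested.

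With the correlation between genes estimated, camera called 1 list at 2 weeks and 0 in the other 8 comparisons. With fry, which tests a list against no change rather than against other genes, the lists called were 1 at 2 weeks, 2 at 4 weeks, 11 between 2 and 4 weeks, 1 in the myocardium, and 0 between 4 and 7 weeks, in the aorta and in both comparisons between tissues; at 7 weeks they were 15 in place of 20. With list members also matched by gene number, lists newly called were matrix proteases and inhibitors at 2 weeks, interferon response at 4 weeks and for valve against myocardium, NOTCH and WNT signalling between 4 and 7 weeks and oxidative phosphorylation in the aorta, while the Schwann cell list at 4 and 7 weeks and interferon response at 7 weeks were no longer called; the cause is the members added. With the controls split, the correlation of the diet effect was 0.142 for 2 and 4 weeks in place of 0.346 and 0.467 for 4 and 7 weeks in place of 0.735, with 2 controls in place of 4 in each comparison. Genes present in valve and myocardium but not in aorta numbered 1213 at 1 read, 1199 at 10 reads, 1020 at 1 CPM and 685 by filterByExpr, in place of the 346 removed.

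Directions reversed in 25 values, for lists by the rank that camera gave, and the cause was not tested. With the adipocyte score endothelial genes at 4 weeks had a median of 0.11. With the cardiomyocyte score oxidative phosphorylation had -0.28 at 7 weeks and -0.23 between 2 and 4 weeks, and fatty acid oxidation -0.38 between 2 and 4 weeks. With the atrial score MYH8 at 4 weeks stood at -1.13 and MYBPHL at 7 weeks at -2.25, mesothelial and epithelial genes at -0.54 at 4 weeks and -0.79 at 7 weeks, and oxidative phosphorylation at -0.58 at 7 weeks. With the erythroid score endothelial genes at 7 weeks ranked lower at a median of 0.0380, and immediate early genes had 0.43 between 4 and 7 weeks. With the share of RN18S cholesterol biosynthesis had 0.26, oxidative phosphorylation 0.0148 and cardiomyocyte genes 0.0448 at 4 weeks; cholesterol biosynthesis 0.42, interferon response -0.12, matrix proteases -0.25 and endothelial genes -0.31 between 2 and 4 weeks; and leukocyte adhesion 0.36, extracellular matrix 0.19, cell cycle 0.78, oxidative phosphorylation -0.12 and cardiomyocyte genes -0.47 between 4 and 7 weeks. Immediate early genes in the aorta had -0.26 with the replicate block and -0.27 without control replicate 3, and leaving out each library gave -0.271 to 0.281.

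Leaving out each library in turn gave 0 to 437 genes at 2 weeks, 0 to 794 at 4 weeks, 460 to 2283 at 7 weeks, 220 to 1248 between 2 and 4 weeks and 4 to 54 between 4 and 7 weeks. It gave 2 to 284 in the aorta, where a lone diet library is assumed to vary like the controls, 1 to 36 in the myocardium, 5 to 179 for valve against myocardium and 0 to 9 for valve against aorta. Lists called were 11 to 15 at 2 weeks, 21 to 23 at 4 weeks, 17 to 24 at 7 weeks, 16 to 20 between 2 and 4 weeks, 8 to 15 between 4 and 7 weeks, 4 to 10 in the aorta, 9 to 13 in the myocardium, 8 to 12 for valve against myocardium and 11 to 18 for valve against aorta. Correlations were 0.286 to 0.484 for 2 and 4 weeks, 0.0384 to 0.268 for 2 and 7 weeks and 0.660 to 0.782 for 4 and 7 weeks. The cause was not tested.

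On simulated counts with the depth and spread of these libraries, edgeR recovered 13% of 2-fold changes in the aorta and 5% in the myocardium, so most 2-fold changes there would not be called.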
